A study of Mus musculus with 62 samples.

How the data were processed

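Single cells of KPC1199-EGFP, a mouse pancreatic cancer line of C57BL/6 origin, were profiled by RNA sequencing from an untreated adherent culture at passage 9. Per the labels' protocols, the cells were trypsinised, captured and amplified on a medium-sized chip of the Fluidigm C1 system, and made into libraries with Nextera XT. The labels give 62 libraries, each from 1 cell, and 1 culture. They therefore form 1 group with no replicate culture, and no comparison between groups was made. No p-value per gene was computed from cells. Permutation p-values for correlations across cells speak of the cells of this culture alone.

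The deposited values are estimated counts per gene symbol, made by the authors with kallisto for mouse build mm9, per the submitters' processing notes. The version, the annotation, and how transcript estimates became gene rows are not given in the sources used here. Of the values above 0, 66.18% were whole numbers within 1e-06. The table held 19177 rows, of which 65 were ERCC spike-in sequences, synthetic RNAs added in known amount, and 19112 were genes. No mitochondrially encoded gene had a row, and EGFP was not analysed here. Symbols altered by table software were restored where the result was a known symbol. In this way 17942 symbols matched as given, 1092 matched after restoring, and 78 stayed unmatched and kept the name in the table. The reference annotation in use was of another build, so no coordinates are printed.

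Spike-in rows were left out of library sizes. Counts were scaled to CPM by the sum of the gene rows and log2-transformed with a pseudocount of 1. Estimated counts were used unrounded, except for thinning, where they were rounded to whole numbers first. No count model was fitted. Genes above 0 in at least 10 libraries were tested, which left 12143 genes. Variability was the residual of the log2 squared coefficient of variation over a lowess trend (fraction 0.3) on mean log2 level. Gene lists for 16 programs, 6 other cell types and the tumour genotype were fixed before the data were examined, as were the tests and the rule for named genes. Each list's median residual and mean pairwise Pearson r were ranked among 10000 random lists of the same size, matched on expression in 10 bins. A list was called at the 99th percentile. A list score was the mean z value of its members minus that of all tested genes in the same bins. Scores were compared in 15 pairs by two-sided permutation tests with 100000 resamples and Benjamini-Hochberg adjustment at 0.05. The smallest p such a test can give is 1e-05. Principal components used the 1000 most variable genes. Label numbers, which run from 1 to 96, were split into 8 blocks of 12 as a possible technical batch. Shares of libraries carry exact Clopper-Pearson 95% intervals, which cover the sampling of cells only. No doublet caller was run, and no library was removed from the main results.

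The named genes were the 20 of highest mean level outside ribosomal protein genes, the 25 of largest variability residual, and all genes of the genotype list. From each program list came the 4 of highest mean and the 2 of largest residual, and from each other cell type the 2 found in most libraries. The 10 leading genes at each end of components 1 and 2 completed the rule. A gene of the genotype list that this rule takes is not reported here. Any other gene named in the text was chosen after its values were seen. The same holds for the split of libraries at a spike-in share of 20%, which was added because the libraries fell into 2 sets on that share.

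The computations were tested on simulated counts drawn from the real gene means and library sizes, with 200 genes raised in 20% of the libraries. With all 62 library sizes and 12130 genes, 56.7% of the 67 genes raised 2-fold lay above the 95th percentile residual of unchanged genes, as did 100% of the 67 raised 4-fold and 100% of the 66 raised 8-fold. All 20 planted coherent lists were called (100%), and 3% of the 100 lists with no shared factor were called. Changed and planted genes were taken from those of higher mean level. The shared factor had an SD of 1 on the log2 scale, against gene noise of 0.5. All simulated libraries shared 1 mean profile. The differing profiles of the 12 libraries with a spike-in share of 20% or more were not modelled. Noise was the same for every gene, with no zeros beyond those of count sampling, whereas many genes in the other 50 spread more widely. The simulated rates may therefore not hold over the real 62 libraries or over the 50. For 10 score pairs simulated with a correlation of 0.6, the median r was 0.588. Of 500 simulated pairs with no correlation, 6.2% had an unadjusted p under 0.05. On the real values, 10.3% of 600 pairs of random matched lists had one over all 62 libraries, and 8.83% over the 50 libraries with a spike-in share under 20%. Random lists were thus correlated with each other more often in these data than in the simulation. A permutation p for a score pair therefore overstates how far that pair stands out from random lists.

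The alternatives, whose effect the closing section gives, were pseudocounts of 0.1 and 10, minimum detection in 3 or 31 libraries, and median-of-ratios scaling over the 182 genes above 0 in every library. Others left out ribosomal protein genes, kept the 52 libraries with at least 50% of the median number of detected genes, or regressed that number out. Scores were also taken with no subtraction or centred within blocks, components over 500 or 2000 genes, and detection at 1 CPM. Thinning each library to 100000 gene counts and keeping spike-in shares under 20% were added after the data were seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.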

Results

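The study used cultured KPC1199-EGFP cells as a control for a method that reads genomic DNA and RNA from the same cell. The series' design text states that these cells were at the passage at which the line was injected into mice. The data comprised 62 single-cell libraries of 1 culture, so the report describes levels and spread over cells and makes no comparison between groups. Gene counts per library had a median of 6801460 and ranged from 112196 to 12868800. A median of 8553 genes per library had a count above 0, and the range was 892 to 11068. After thinning to 100000 gene counts per library the median was 6306.5 genes. No pair of libraries held identical values, and the highest pairwise correlation of log2 levels was 0.903, between libraries 20 and 43.

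Spike-in sequences divided the libraries into 2 sets. In 50 libraries they took 0.19% to 1.83% of all counts, and in the other 12 they took 22.3% to 97.2%. The 50 libraries had a median of 8830.5 detected genes and between 2153900 and 12868800 gene counts. Among the 12, library 43 differed from the rest, with 9041 detected genes at a spike-in share of 71.1%. Levels below are therefore also given for the 50 libraries, as mean ± SD of log2(CPM + 1) over cells of 1 culture.

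**Figure D1:**
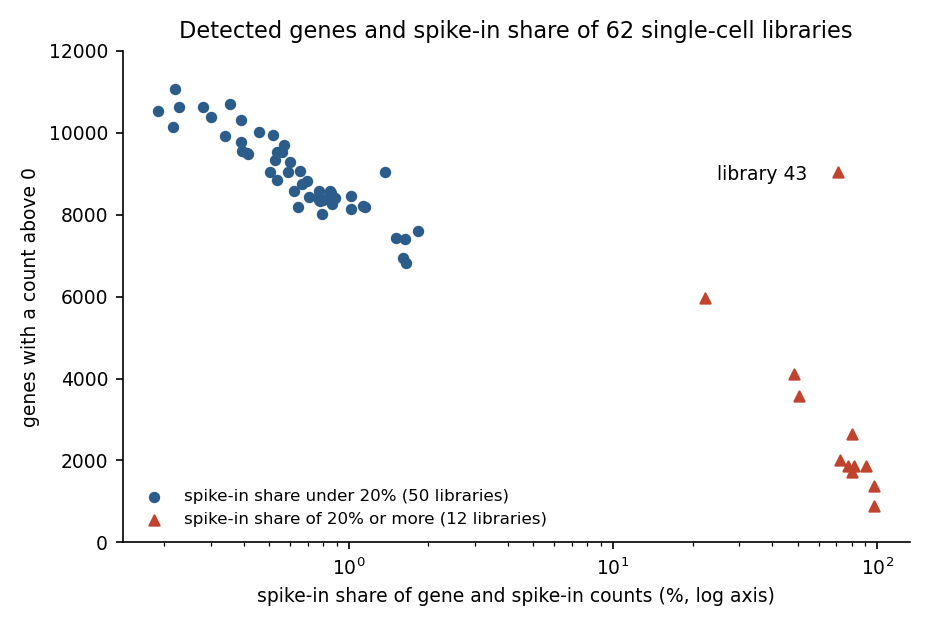
Each point is 1 of the 62 libraries, placed by its spike-in share in percent on a log axis and its number of genes with a count above 0. The 50 libraries under 20% (circles) lie between 6832 and 11068 genes, and the 12 others (triangles) lie below them except for library 43.

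The first question was which genes these tumour cells expressed. The highest levels outside ribosomal protein genes belonged to Ftl1, the ferritin light chain, at 13.31 ± 0.39 (SD, n = 50), and Spp1, the secreted phosphoprotein osteopontin, at 13.14 ± 1.81. Ppia, Gapdh and S100a6 followed at 12.66 ± 0.37, 12.48 ± 0.44 and 12.46 ± 0.42. Over all 62 libraries Ftl1 stood at 12.78 ± 2.10 and Spp1 at 12.24 ± 2.90. Rapgef4 and the ribosomal RNA gene Rn45s were among the 20 highest of the 62 libraries, and both took larger shares in the 12 spike-in-rich libraries. The median share of Rapgef4 was 7.18% of gene counts there and 0.131% in the 50.

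All 10 measured genes of the tumour genotype list were above 0 in at least 50% of the 62 libraries. Trp53, which encodes the tumour suppressor p53, was above 0 in 54 of 62 libraries (87.1%, interval 76.1 to 94.3). In the 50 libraries it stood at 7.87 ± 0.70. Cdkn2a and Smad4, tumour suppressors often lost in pancreatic cancer, were above 0 in 49 and 48 of 62 libraries. Myc was above 0 in 50 libraries and the pancreatic transcription factor Pdx1 in 45. These counts do not read the sequence, so they carry no information on alleles.

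Proliferation and cholesterol synthesis genes were widely detected. All 39 S phase genes and 49 of the 50 G2 and M phase genes were above 0 in at least 50% of the 62 libraries. Pcna, the DNA polymerase clamp, stood at 9.41 ± 0.86 in the 50 libraries and the chromatin protein Hmgb2 at 9.92 ± 0.98. All 20 cholesterol synthesis genes passed the same mark, led by Fdps at 10.07 ± 1.08 and Msmo1 at 9.38 ± 1.48. Glycolysis and hypoxia genes passed it in 20 of 23 cases, with Ldha at 11.56 ± 0.51. In all, 266 of the 371 list entries measured for the 16 programs were above 0 in at least 50% of the 62 libraries. With detection at 1 CPM the count was 249. Of all 19112 gene rows, 8541 were above 0 in at least 50% of the 62 libraries.

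Epithelial and mesenchymal genes were both present. Keratins were high: Krt18 stood at 11.11 ± 0.63, Krt8 at 10.99 ± 0.72 and Krt19 at 10.87 ± 0.92 (n = 50). The adhesion gene Cdh1 was above 0 in 58 of 62 libraries. The intermediate filament gene Vim, a mesenchymal marker, was also above 0 in 58, at 9.31 ± 0.73 in the 50. Of the measured members, 14 of 23 epithelial and 15 of 26 mesenchymal genes were above 0 in at least 50% of the 62 libraries. With detection at 1 CPM these counts fell to 11 and 12. Some members were rare. Epcam, chosen after its values were seen, was above 0 in 20 of 62 libraries. The mesenchymal genes Mmp2 and Lox, chosen in the same way, were in 0 of 62, and 0 of the 50 with a low spike-in share allows a share of up to 7.11% of cells.

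Lists for pancreatic identity and tumour subtype were detected in part. Of 14 duct genes 10 were above 0 in at least 50% of libraries, among them Spp1, Krt19, Krt7 and Muc1. The classical subtype list reached that mark for 9 of 17 genes. Plac8 stood at 10.19 ± 0.61, Lgals4 at 10.07 ± 2.19 and Tspan8 at 9.44 ± 0.73 in the 50 libraries. The basal-like list reached it for 10 of 21 genes, led by Anxa8 at 8.87 ± 0.75 and Cd44 at 7.04 ± 1.28. Its squamous keratins Krt5, Krt14 and Krt17, chosen after their values were seen, were above 0 in 3, 2 and 3 of 62 libraries.

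Signalling and stress lists varied in how fully they were detected. Immediate early genes were above 0 in at least 50% of libraries for 18 of 21 members, with Fos at 7.76 ± 2.46. The counts were 14 of 19 for RAS-MAPK output, with Ccnd1 at 7.60 ± 0.94, and 15 of 18 for the unfolded protein and amino acid response. For p53 targets the count was 10 of 20, with Bax at 7.05 ± 0.62. All levels were read after the cells had been trypsinised and captured. What those steps added, to immediate early genes among others, was not tested.

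Immune-related lists were detected in part. The interferon response list reached the mark for 7 of 25 genes (5 with detection at 1 CPM), and its highest member, Ifi27, stood at 4.79 ± 2.04. MHC class I genes reached it in 7 of 12 cases (6 with detection at 1 CPM), with H2-T23 at 8.14 ± 1.07 and B2m at 8.12 ± 0.62. The immunoproteasome gene Psmb8 and the MHC class I activator Nlrc5, chosen after their values were seen, were in 0 of 62 libraries. Among cytokines and immune ligands the count was 9 of 23, and with detection at 1 CPM it was 7. Cd47 stood at 7.98 ± 0.89 and the chemokine gene Cxcl5 at 7.48 ± 2.85.

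Most measured markers of other cell types were near 0. The median member of the immune, fibroblast and acinar lists had a mean of 0 over the 62 libraries. Of the 13 immune genes measured, 8 were in none of the libraries, as were 5 of 11 endothelial, 8 of 11 fibroblast, 4 of 7 acinar, 2 of 4 endocrine islet and 2 of 8 red blood cell genes. Rows were present for 7 of 15 listed acinar and 4 of 10 listed islet markers, so the others could not be read. In at least 50% of the libraries 1 immune and 1 fibroblast gene were above 0, and 0 of the other lists. Col1a1 was above 0 in 49 of 62 libraries at 0.33 ± 0.26 in the 50, and Itgam in 32 at 0.22 ± 0.33. Egfl7 was above 0 in 20 and Prss2 in 19, at 1.73 ± 2.37 and 1.29 ± 1.94. With detection at 1 CPM, 0 genes of the 6 lists were found in at least 50% of libraries.

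**Figure D2:**
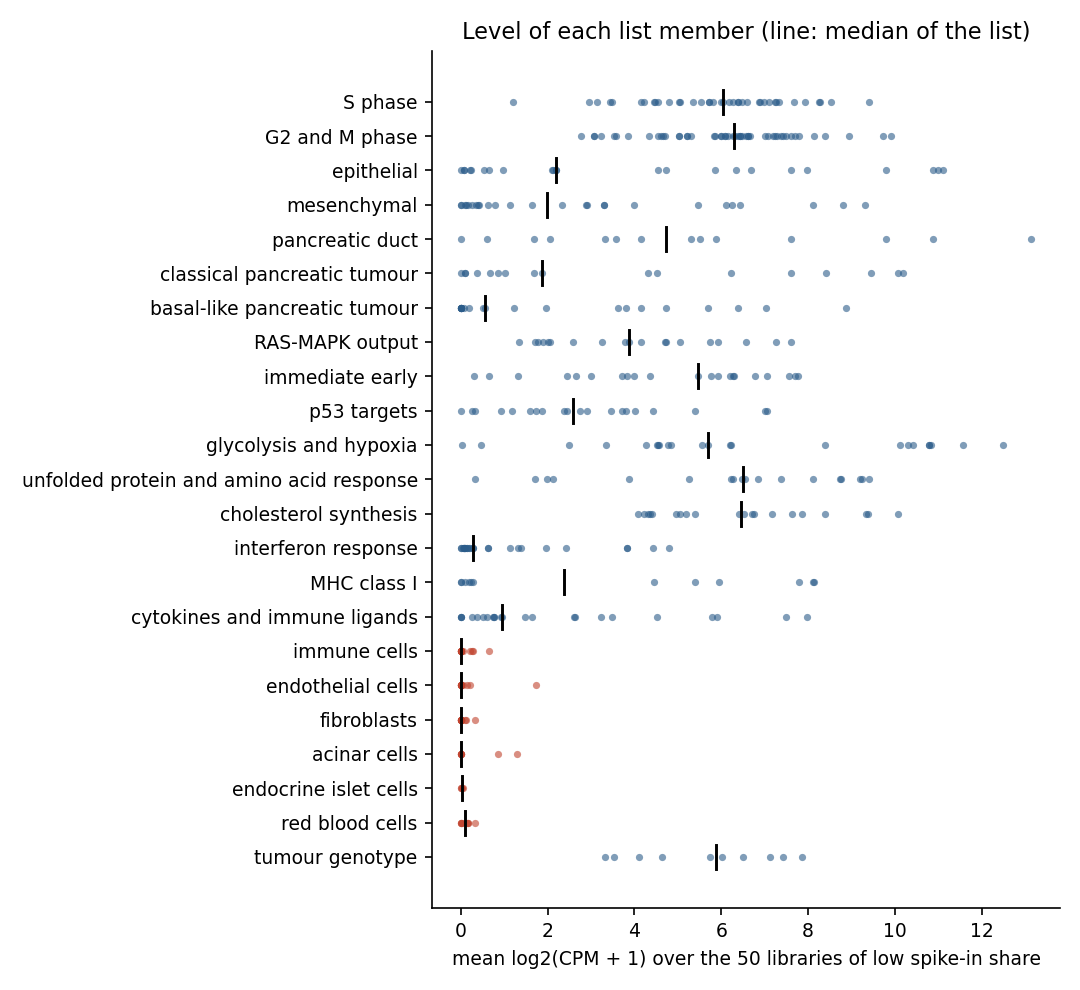
Each point is 1 gene of a list, at its mean log2(CPM + 1) over the 50 libraries with a spike-in share under 20%, and black lines mark list medians. Markers of other cell types (red) reach at most 1.73, and members of the program and genotype lists (blue) reach 13.14.

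The next question was which genes differed most from cell to cell. Over all 62 libraries the largest residuals belonged to Metap2, Dctn2, Scpep1 and Kpnb1. For each of the 25 most variable genes, 1 library among the 12 spike-in-rich ones held between 58.9% and 92.7% of the summed CPM. None of the 25 was among the 25 most variable of the 50 libraries (0 shared). In the 50, chosen after the data were seen, Spp1 ranked 1 and ranged up to 86975 CPM. Trf, the iron carrier transferrin, ranked 2 at 6.44 ± 3.15, followed by Clu at 11.25 ± 1.22 and Tmsb4x at 12.14 ± 1.09. Krt19 ranked 7 and Cxcl5 ranked 9.

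At the level of lists, 4 of 16 were more variable than matched random lists over the 62 libraries. They were G2 and M phase (percentile 100), mesenchymal (99.9), immediate early (99.8) and epithelial (99.5). Over genes above 0 in at least 31 libraries, epithelial genes were at percentile 98.6, below the mark. Cytokine and immune ligand genes, at 95.4 in the main setting, passed there (99.5) and over genes above 0 in at least 3 libraries (99.7). In the 50 libraries the count was 12 of 16, with p53 targets (10.4), MHC class I (88.2), interferon response (90.7) and RAS-MAPK output (94.8) below the mark.

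Members of 3 lists rose and fell together across the 62 libraries more than matched random lists did. The mean pairwise r was 0.605 for S phase genes, 0.586 for G2 and M phase genes and 0.612 for cholesterol synthesis genes. Random lists were themselves correlated in this set, with medians of 0.430, 0.456 and 0.469. With a pseudocount of 0.1 cholesterol synthesis fell to percentile 97.8, below the mark, and 2 lists were called. In the 50 libraries the random medians were 0.0275, 0.0269 and 0.0259, and the 3 lists stood at 0.437, 0.490 and 0.387. There 10 of 16 lists were called. The additions were immediate early (0.199), classical tumour (0.198), unfolded protein (0.159), glycolysis (0.153), epithelial (0.125), cytokine (0.0980) and mesenchymal genes (0.0654). The last lay close to the mark, at percentile 99.1. Duct and basal-like genes had mean r values of -0.0106 and 0.000721.

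**Figure D3:**
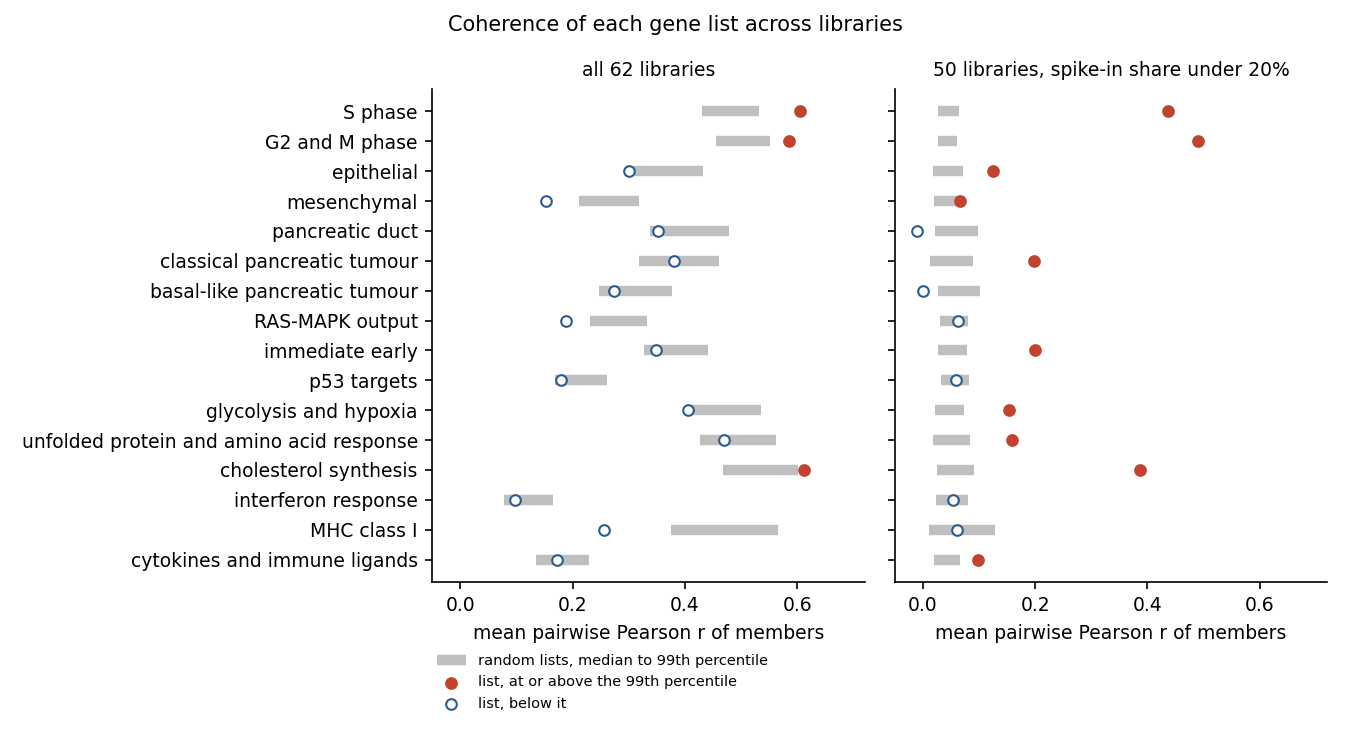
Mean pairwise Pearson r of the members of 16 gene lists (points) over all 62 libraries (left) and the 50 with a spike-in share under 20% (right), with grey bars from the median to the 99th percentile of 10000 matched random lists. Filled points mark 3 lists called on the left and 10 on the right.

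Scores of different lists were then compared across cells in 15 pairs. Over the 62 libraries 0 of 15 pairs passed the adjusted threshold, and 4 had an unadjusted permutation p under 0.05. Because the libraries formed 2 sets, r is given within each set, for the 5 pairs with an unadjusted p under 0.05 over the 62, the 50 or the 12 libraries and for epithelial with mesenchymal scores. In the 50 libraries 0 of 15 passed and 2 had an unadjusted p under 0.05. RAS-MAPK output and immediate early scores had there r = 0.397 and rho = 0.332 (permutation p = 0.00439 and 0.0187, adjusted p = 0.0640 for r). Without the 2 farthest libraries r was 0.306, and within label-number blocks it was 0.359. Scores of p53 targets and G2 and M phase had r = -0.367 and rho = -0.371 (permutation p = 0.00853 and 0.00845, adjusted p = 0.0640 for r). The r was -0.362 without the 2 farthest and -0.353 within blocks. With detected genes regressed out, the same 2 pairs passed in the 50 libraries, at r = 0.399 (adjusted permutation p = 0.0304) for RAS-MAPK output with immediate early and r = -0.443 (adjusted permutation p = 0.0220) for p53 targets with G2 and M phase. Of 600 pairs of random lists matched to the 15 pairs, with no regression, the central 95% in the 50 libraries had r between -0.338 and 0.292. No such range was computed for the regressed scores. Epithelial and mesenchymal scores had r = -0.0875 and rho = -0.174 (permutation p = 0.546 and 0.224, adjusted p = 0.675 for r), with -0.205 without the 2 farthest and -0.107 within blocks. S phase and G2 and M phase scores had r = 0.244 and rho = -0.0878 (permutation p = 0.0864 and 0.545, adjusted p = 0.432 for r), with -0.00613 without the 2 farthest and 0.238 within blocks. Glycolysis and G2 and M phase scores had r = -0.173 and rho = 0.105 (permutation p = 0.229 and 0.465, adjusted p = 0.675 for r), with 0.138 without the 2 farthest and -0.0879 within blocks. Glycolysis and unfolded protein scores had r = 0.133 and rho = 0.236 (permutation p = 0.359 and 0.1002, adjusted p = 0.675 for r), with 0.363 without the 2 farthest and 0.158 within blocks.

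In the 12 spike-in-rich libraries, which had a median of 1940 detected genes, scores used genes above 0 in at least 3 of the 12. Of the 15 pairs 1 passed the adjusted threshold in this set and 2 had an unadjusted p under 0.05. S phase and G2 and M phase scores had there r = 0.857 and rho = 0.713 (permutation p = 0.00076 and 0.0121, adjusted p = 0.0114 for r). That r was 0.617 without the 2 farthest libraries (permutation p = 0.0543). For this set no range from random lists was computed, and detected genes, which spanned 892 to 9041, were not regressed out. The blocks held between 1 and 3 of the 12 libraries, too few to read r within blocks, so it is not given here. Glycolysis and unfolded protein scores had r = 0.602 and rho = 0.434 (permutation p = 0.0372 and 0.161, adjusted p = 0.279 for r), and r was 0.650 without the 2 farthest. RAS-MAPK output and immediate early scores had r = -0.122 and rho = -0.140 (permutation p = 0.707 and 0.667), and r was -0.324 without the 2 farthest. Scores of p53 targets and G2 and M phase had r = -0.0835 and rho = -0.0629 (permutation p = 0.797 and 0.852), and r was -0.0682 without the 2 farthest. For epithelial and mesenchymal scores r was -0.0405 and rho 0.0769 (permutation p = 0.900 and 0.817), and r was -0.188 without the 2 farthest. Glycolysis and G2 and M phase scores had r = -0.169 and rho = -0.175 (permutation p = 0.596 and 0.590), and r was 0.445 without the 2 farthest. The adjusted p for r was 0.958 for each of the last 4 pairs. Differences in r between the 2 sets were not tested.

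Component 1 of the 62 libraries held 28.5% of the variance of the 1000 most variable genes. Eif2s1 and Uqcrc1 led its positive end, and Dpysl2 and Fhl3 its negative end. Within the 50 libraries component 1 held 9.35%. Upk1b, a uroplakin, Plat, the tissue plasminogen activator, and Ly6a led one end, and Tspan13 and Epcam the other. It correlated with the number of detected genes at r = 0.609 and rho = 0.558 (permutation p = 1e-05, the smallest possible, and 5e-05). The r was 0.571 without the 2 farthest libraries and 0.694 within blocks. With log2 gene counts per spike-in count this component had r = 0.731, for which no p-value was computed. Component 2 of the 50 held 7.27% and was led by Nusap1, Sgk1, Cenpe and Ube2c against Upk1b and Tm4sf20. Nusap1, Cenpe and Ube2c are genes of mitosis, and all genes named for the 50 were chosen after their values were seen.

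The number of detected genes was set against the score of each of the 16 lists. Over the 62 libraries 2 lists passed the adjusted threshold, mesenchymal and MHC class I (adjusted p = 0.0454 for both). However, 39.3% of random matched lists had an unadjusted p under 0.05 there. Within the 50 libraries G2 and M phase was the list that passed, with r = 0.429 and rho = 0.388 (permutation p = 0.00183 and 0.00596, adjusted p = 0.0293 for r). It stood at 0.445 without the 2 farthest and 0.428 within blocks, and 9.83% of random lists had an unadjusted p under 0.05. Blocks of label numbers held 7.96% of the variance in detected genes over the 62 libraries (permutation p = 0.706) and 15.9% over the 50 (permutation p = 0.361), and each of the 8 blocks held between 1 and 3 spike-in-rich libraries.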

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

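All tests in this part were chosen after the result was seen. Counts of spike-in sequences drew attention as a signal in data outside the gene measurements. All 65 sequences were counted in at least 1 library. A spike-in share of 20% or more was found in 12 libraries, and the highest share was 97.2%. Among the 12, library 43 had a correlation of 0.901 with the mean profile of the other 50, whose own values ranged from 0.753 to 0.936, and the other 11 lay between 0.178 and 0.501. Its correlation with library 20, one of the 50, was 0.903, the highest of all pairs of libraries. That value used genes above 0 in at least 10 libraries, while the values with the mean profile used all gene rows. Rapgef4 took 5.48% of the gene counts of library 43 and Rn45s 1.95%, against at most 0.273% and 0.417% in the 50 and medians of 7.18% and 1.89% in the 12.

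Fewer sequenced reads would lower spike-in and gene counts alike, but the median spike-in count of the 12 libraries was 27.3 times that of the other 50, while their median gene count was 0.0504 times as high. Little intact cell RNA in the reaction may account for 11 of the 12, which all had fewer genes than every one of the 50 libraries thinned to the same gene count (library 56 by a small margin, 5951 against 5970 genes). For library 43, with 9031 genes after rounding, a mixture of transcripts from many cells is neither shown nor excluded, since 6 of the 50 libraries thinned to its gene count had at least as many genes. An equal pool of the 50, added after that result, gave 10956 to 11033 genes in 20 draws. What library 43 held, and whether the other reactions held a broken cell or none, stays open, and no biological explanation was tested.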

How the results depend on the processing

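The settings that keep the 50 libraries with a spike-in share under 20%, and thinning, were chosen after the data were seen. Of the main results, 29 alternatives gave the same call or a count within 1.5 times, 14 gave more or newly passed and 3 gave fewer or no longer passed. Of the values for single genes, lists and pairs, 846 stayed the same, 26 moved, 55 newly passed, 2 no longer passed and 2 reversed by the counting rule used. More score pairs than these 2 changed sign, as given below. Coherent lists numbered 3 in the main setting, 2 with a pseudocount of 0.1, where cholesterol synthesis was lost at percentile 97.8, 5 in the libraries with at least 50% of the median detected genes, 9 with detected genes regressed out, and 10 in the 50 libraries with or without that regression. Variable lists numbered 4, against 13, 9 and 12 in the 52 libraries, under median-of-ratios scaling and in the 50. Epithelial genes were lost at percentile 98.6 with detection in at least 31 libraries. Cytokine and immune ligand genes newly passed with detection in at least 31 libraries (99.5) and in at least 3 (99.7). Score pairs past the threshold numbered 0, against 1 with a pseudocount of 10, 1 in the 52 libraries, 1 under median-of-ratios scaling, 2 with detection in at least 31 libraries, 2 in the 50 with detected genes regressed out, and 15 with no subtraction. RAS-MAPK output with immediate early was among those that passed in each of these settings, and p53 targets with G2 and M phase was the other where 2 passed. Lists tied to depth numbered 2, against 16 with no subtraction and 1 in the 50. Mesenchymal and MHC class I, the 2 of the main setting, no longer passed in the 50 (adjusted permutation p = 0.658 and 0.361). They are not among the 2 losses counted above. With no subtraction the correlation of p53 targets with G2 and M phase turned to 0.634, and that of epithelial with mesenchymal scores to 0.589. Every other pair with a negative r in the main setting turned positive too, among them glycolysis with G2 and M phase (-0.269 in the main setting). Unsubtracted scores all followed the number of detected genes, so these values carry that shared trend. Component 1 correlated with detected genes at 0.963 over all 62 libraries, where the 2 sets lie apart, and at 0.121 in the 52 (permutation p = 0.380). The latter was -0.718 without the 2 farthest libraries. Of the 25 most variable genes, 0 were shared with the 50. Apart from the cases named, the cause was not tested. No paired analysis was possible because the labels give 1 group. A gene in 0 of 50 libraries leaves room for a share of up to 7.11% of cells (exact limit, for sampling of cells only).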

Other observations

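The tests in this part were chosen after the result was seen, except that of the X-linked homologues, which was fixed before those values were looked at. Genes named here were chosen after their values were seen. Among the genes that varied most over the 50 libraries with a low spike-in share, Lgals2, a galectin, stood at 9.88 ± 1.82 (SD of log2 level, n = 50). The tissue factor gene F3 stood at 7.59 ± 1.58, the aldo-keto reductase Akr1b8 at 8.20 ± 1.09 and the metallothionein Mt1 at 7.43 ± 1.28. Bnip3, a hypoxia-responsive gene, was above 0 in 45 of the 50 and reached 2285 CPM. Sprr1a, a cornified envelope gene, was above 0 in 21 of the 50 and reached 3211 CPM. No shared theme was tested for these genes.

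Of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, all 4 were at 0 in 24 of the 50 libraries and at least 2 were found in 18, with a median summed level of 81.9 CPM (range 0.114 to 293) where any was found. Among the 50, libraries 10, 17, 25, 30, 35, 39, 47 and 48 held at most 0.324 CPM. All others with a count held at least 36.5 CPM. Library 17, at 0.222 CPM, is among the 18, and library 24, with 1 gene at 36.5 CPM, is not. Low depth as the only source of their joint variation is argued against. With detected genes regressed out their mean pairwise r was 0.559, at percentile 100 of 10000 matched sets of 4 genes, whose highest was 0.281. Yet the 6 libraries with all 4 genes had 9029 to 11068 detected genes, all above the median of 8830.5. Libraries with none had 6832 to 10308, and those with any had 6935 to 11068. A part for depth or RNA content in whether the genes were found is therefore not excluded. Reads shared with the X homologues are argued against, since 54.2% of the 24 libraries with no Y-linked count were above the median X homologue level. The rank correlation of the summed levels was -0.0437 (permutation p = 0.764). What set the libraries with no Y-linked count, or at most 0.324 CPM, apart stays open, and no biological explanation was tested.

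The hypothesis that cells with a high G2 and M phase score hold more RNA was examined because that score had been seen to follow the number of detected genes. Gene counts per spike-in count, which spanned 53.6 to 524 over the 50 libraries and itself followed detected genes at r = 0.919 and rho = 0.910 (permutation p = 1e-05 for both, the smallest possible), had on a log2 scale r = 0.531 and rho = 0.493 with the score (permutation p = 8e-05 and 0.00043, adjusted p = 0.00128 for r over the 16 lists). The r was 0.507 without the 2 farthest libraries and 0.548 within blocks, and lay at percentile 99.9 of random lists matched to this one. With detected genes regressed out, r was 0.383 (permutation p = 0.00566, adjusted p = 0.0906), so the relation no longer passed the threshold, and RNA content and detection cannot be told apart here because the measures overlap so closely.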
